A study of Mus musculus with 9 samples.

How the data were processed

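RNA sequencing was analysed for 9 liver libraries of Swiss mice in 3 groups of 3: untreated controls, mice given β-CYP at 40 mg/kg, and mice given the same dose of β-CYP together with sodium selenite (Na2SeO3) at 50 µg/kg. The labels do not spell out β-CYP, and the abbreviation is used here as given. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a TruSeq RNA kit. The series' design text names an Illumina HiSeq instrument, whereas the library protocol names a BGISEQ one, and nothing in the values settles which was used. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

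The authors deposited one table of log2 values for 25781 genes, each with an Ensembl identifier and a symbol, with a column for each library. Per the submitters' processing notes, HISAT, Cufflinks and the genome build mm9 were used, with no versions, roles or order given. The annotation and the counting tool are not given in the sources used here. The deposited log2 values were checked and equal the log2 of a read count divided by a factor of its library, plus 1. Undoing that transformation gave whole reads, within 0.02 of a whole number, for 100% of the values in each of the 9 libraries. The factors equal median-of-ratios factors computed from the recovered reads, within a tolerance of 1e-09 in 9 of 9 libraries. The authors' normalization thus makes the typical gene equal between libraries and assumes that most genes do not change. The values are called scaled counts. Recovered totals ran from 28630269 to 36029560 reads per library, and 15395 genes were above 0 in all 9. Of the identifiers, 25731 match the GENCODE annotation of another build (GRCm38) and 50 do not. Since the submitters name mm9, gene names alone were used and no coordinates are given. A symbol was shared by 68 entries.

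Tests were run with limma 3.58.1 in R 4.3.3. One linear model of 3 group means was fitted to log2(scaled count + 1) over all 9 libraries, with an intensity trend in the empirical Bayes step, for genes with a mean scaled count of at least 1. The tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes on this scale understate the change of genes with few reads. The design had been written, before the data were examined, for FPKM or another normalized unit, with FPKM expected. For a table of counts it set edgeR's quasi-likelihood test as the main test, and this was not run. The test for normalized units and its minimum of 1 FPKM were kept literally, and applied to scaled counts. Gene lists of liver pathways, cell types and other tissues, 43 of which had at least 5 tested members, were also fixed before the data were examined. They were tested with limma's camera with a preset correlation of 0.01, which compares a list with the other genes, and adjusted over the 129 tests of the 3 comparisons together. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were run beside it. The genes to be named were set by a rule fixed at the same time: the 8 largest rises and the 8 largest falls per comparison among genes whose groups do not overlap, the leading and passing members of each list, and 15 genes fixed in advance. The rule admits 563 genes, of which the text names 123 as examples, including the 8 rises and 8 falls of each comparison and the 15 fixed genes. Some genes that the rule admits were left out of the text because they are withheld for evaluation. Markers of islets and spermatids were added after the data were seen.

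For a gene with 0 reads in a group, the fold is a bound computed with 3 counts per library in place of 0. For a group with 1 to 3 reads, the ratio has a 95% exact counting interval. Reads are not independent molecules, so these bounds and intervals cover counting error only. How the counting treated reads shared by near-identical genes is not given in the sources used here. Values of Saa1, Saa2, Hspa1a, Hbb-bs, Selenbp2 and the Mup, Amy2a, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a and H2 genes are therefore uncertain for single members. Other genes with close relatives may be affected too. Overlapping and antisense genes cannot be told apart without the strand setting. At 1000 to 10000 scaled counts, the median coefficient of variation within a group was 3.64% to 3.92%, against 1.69% to 1.85% for counting error. At 100 to 1000 it was 7.99% to 8.20%, against 4.27% to 4.46%.

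The model was tested on simulated counts drawn from the real means and depths, with 50 genes changed at each size. The changed genes had a mean scaled count of at least 10, so the shares do not cover tested genes with fewer counts. Far fewer genes were changed than passed in the data, which also affects the adjusted threshold. In the comparison of β-CYP with control, over 19514 genes tested, it recovered 6% of genes changed 1.25-fold, 38% at 1.5-fold, 70% at 2-fold and 90% at 4-fold. In the comparison of selenite with β-CYP, over 19478 genes, the shares were 2%, 32%, 66% and 86%. In that of selenite with control, over 19502 genes, they were 0%, 28%, 76% and 88%. Among unchanged genes, 10 of 19290, 7 of 19254 and 6 of 19278 were called. The 1 changed list was called each time and no other list was. The draw used means and depths and did not copy the correlation between genes. It therefore cannot show how often the list test calls unchanged lists in the real data. There, splits of the libraries that mixed the groups still called at most 6, 11 and 13 lists in these comparisons, in the same order. Such splits are uneven and keep part of the real difference between the groups, so these counts do not measure false calls either.

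Alternatives fixed before the data were examined were other pseudocounts, filters, scalings between libraries, fits, gene set tests and a block for the replicate number, and each library was left out in turn. The scalings were quantile normalization, equal medians, equal totals, and an equal mean of the tested genes without the 1% with the highest mean (called trimmed-mean scaling). Alternatives chosen after seeing the data were limma's voom on the recovered reads, a minimum mean of 10, a fold of at least 2, and leaving out genes seen in the selenite group alone. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.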

Results

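Liver transcriptomes were compared between 3 groups of mice, with 3 libraries each. The series concerns selenium against liver injury, and its design text calls the group given β-CYP the injury group and the group given β-CYP with sodium selenite the repair group. These are called the β-CYP group and the selenite group here. Libraries held 28630269 to 35821336 reads in control, 32052250 to 36029560 in β-CYP and 32084480 to 33056400 in selenite. Albumin mRNA made up 6.01% to 6.63%, 7.44% to 7.72% and 6.37% to 6.44% of reads in the 3 groups in that order, and mitochondrial transcripts 7.91% to 8.18%, 5.68% to 5.79% and 6.67% to 6.88%. Spearman correlations over the genes were 0.974 to 0.980 for the 9 pairs of libraries within a group and 0.953 to 0.968 for the 27 pairs between groups. The first principal component held 31.7% of the variance and the second 16.8%. Control replicate 2 differed from the other controls in ribosomal and small RNA transcripts. AY036118, an rRNA-like transcript, had 1805976 reads there against 43988 and 42232, and the 10 most abundant genes took 25.1% of its reads, against 18.6% and 18.8%. Scaling to equal totals counts these reads and so lowers the other genes of that library. This can widen their spread within control, which enters all 3 comparisons through the shared fit. Its part in the calls lost with equal totals was not tested.

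**Figure D1:**
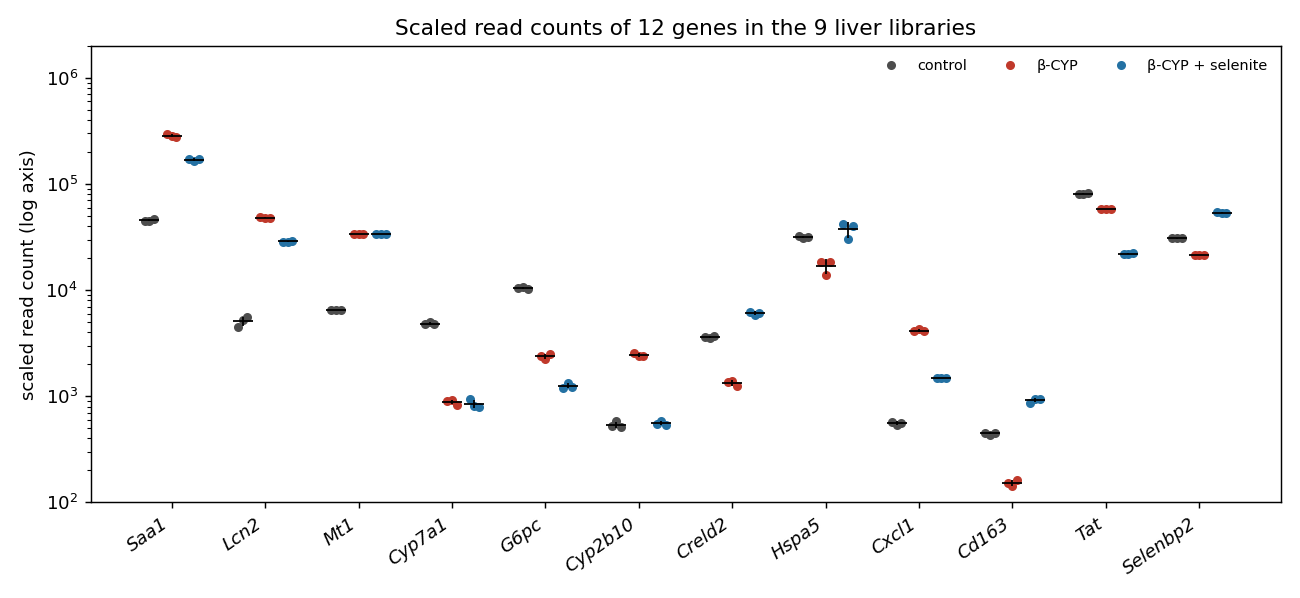
Scaled read counts on a log axis for 12 genes, with a point for each library, and black marks for the mean and SD of the 3 libraries of a group. Saa1, Lcn2 and Cxcl1 were highest in β-CYP, Mt1 stood at 33704 in β-CYP and 33793 in selenite, and Tat fell from control to β-CYP to selenite.

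The first comparison, β-CYP with control, asks what β-CYP changes in the liver. Transcripts of serum amyloid A and other acute phase proteins, which the liver releases in inflammation, were higher in β-CYP. Saa1 went from 45628 ± 1008 to 286208 ± 7352 scaled counts (mean ± SD, n = 3), and Lcn2, a siderophore-binding lipocalin, from 5087 ± 522 to 48066 ± 417. The metal-binding metallothionein Mt1 rose 5.18-fold (limma adjusted p = 1.1e-12). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 4844 ± 120 to 883 ± 45.4 scaled counts (adjusted p = 1.0e-08), and G6pc, the last enzyme of glucose release, from 10532 ± 213 to 2372 ± 146. In limma's test, 3285 of 20145 genes passed (16.3%), 1556 higher and 1729 lower, of which 374 and 399 differed at least 2-fold. The split was 1340 and 1984 with equal medians, 1245 and 1318 with equal totals, and 1740 and 1588 with trimmed-mean scaling, where more genes were higher than lower. The 3 libraries of each group did not overlap for 6368 genes (31.6%, against 10% by chance), among them 3279 of those that passed and all 60 that passed among the 64 named for this comparison. Log2 changes are given with the standard error of limma's model, n = 3 per group.

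Of the acute phase list, 23 of the 26 tested members rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 change 0.88, camera adjusted p = 5.0e-37. Examples were Saa2 (log2 change 2.80 ± 0.027) and Serpina3n, a protease inhibitor (1.97 ± 0.017). In the list of metallothioneins and zinc transport, 5 of the 7 tested members rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 change 0.79, camera adjusted p = 1.1e-06, including Mt2 (2.30 ± 0.022) and the zinc importer Slc39a14, which rose 2.29-fold. Neutrophil markers were 5 up and 0 down of 10 (6 and 0 adjusted over the list alone, median log2 change 1.63, camera adjusted p = 2.4e-04). The calcium-binding alarmins S100a8 (2.79 ± 0.25) and S100a9 (2.50 ± 0.23) rose. The immediate early genes also passed, 6 up and 2 down of 16 (8 and 2 adjusted over the list alone, median log2 change 0.50, camera adjusted p = 6.7e-04), with the transcription factor Egr1 at 1.57 ± 0.066. Interferon response genes were 8 up and 2 down of 26 (15 and 2 adjusted over the list alone, median log2 change 0.26, camera adjusted p = 0.00107). For the inflammatory cytokines, 6 of the 21 tested members rose and 1 fell (6 and 1 adjusted over the list alone, median log2 change 0.44, camera adjusted p = 0.00266, and adjusted p = 0.0582 with an estimated correlation). The neutrophil attractant Cxcl1 rose by 2.89 ± 0.043 and the T cell attractant Cxcl9 by 2.63 ± 0.10. Stellate cell and fibrosis genes were 5 up and 0 down of 18 (8 and 0 adjusted over the list alone, median log2 change 0.23, camera adjusted p = 3.1e-04). Timp1, an inhibitor of matrix proteases, had 0 reads in the controls and was at least 24.8-fold higher in β-CYP, and Acta2, the smooth muscle actin of activated stellate cells, rose by 0.91 ± 0.12.

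In the list of PPARA targets and fatty acid oxidation, 18 of the 32 tested members rose and 3 fell (19 and 4 adjusted over the list alone, median log2 change 0.22, camera adjusted p = 1.7e-07). The pantetheinase Vnn1 was at 1.18 ± 0.14, the acyl-CoA thioesterase Acot1 at 0.93 ± 0.18 and the lipid droplet protein Plin2 at 0.87 ± 0.025. Bile acid synthesis and transport went down, with 3 up and 9 down of 19 (4 and 9 adjusted over the list alone, median log2 change -0.14, camera adjusted p = 4.4e-05). Besides Cyp7a1, the sterol hydroxylases Cyp7b1 (-1.10 ± 0.028) and Cyp8b1 (-0.83 ± 0.025) and the bile salt export pump Abcb11 (-0.72 ± 0.028) fell. Glucose metabolism genes were 3 up and 11 down of 15 (3 and 11 adjusted over the list alone, median log2 change -0.48, camera adjusted p = 5.1e-07), among them Pck1, which feeds gluconeogenesis and fell from 104972 ± 1736 to 52521 ± 335 scaled counts. Cholesterol synthesis was 5 up and 11 down of 24 (5 and 13 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 7.2e-04). The decarboxylase Mvd was at -0.67 ± 0.089. Lipogenesis was 2 up and 7 down of 19 (3 and 9 adjusted over the list alone, median log2 change -0.13, camera adjusted p = 0.00369, and adjusted p = 0.103 with an estimated correlation). Most genes of the unfolded protein and integrated stress list fell: 4 of the 25 tested members rose and 17 fell (4 and 18 adjusted over the list alone, median log2 change -0.31, camera adjusted p = 4.8e-10). Hyou1 (-1.17 ± 0.035), Creld2 (-1.44 ± 0.050) and Hspa5 (-0.91 ± 0.13) fell, whereas Chac1, a glutathione-degrading enzyme of the integrated stress response, rose by 1.35 ± 0.17. Heat shock genes were 1 up and 7 down of 15 (1 and 7 adjusted over the list alone, median log2 change -0.16, camera adjusted p = 2.9e-04), with the inducible chaperone Hspa1a at -1.23 ± 0.087. Male-biased liver genes were 2 up and 12 down of 19 (2 and 13 adjusted over the list alone, median log2 change -0.31, camera adjusted p = 2.9e-09), with the steroid dehydrogenase Hsd3b5 at -1.79 ± 0.040.

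The remaining lists that passed did so with camera's preset correlation but not with an estimated one. Hepatocyte markers were 10 up and 1 down of 18 (11 and 1 adjusted over the list alone, median log2 change 0.12, camera adjusted p = 1.2e-07, and adjusted p = 0.129 with an estimated correlation). Cytosolic ribosomal proteins were 11 up and 0 down of 24 (14 and 0 adjusted over the list alone, median log2 change 0.11, camera adjusted p = 4.4e-07, and adjusted p = 0.0661 with an estimated correlation), with the stalk protein Rplp0 at 0.72 ± 0.028. The circadian list was 2 up and 6 down of 18 (2 and 9 adjusted over the list alone, median log2 change -0.22, camera adjusted p = 0.0233, and adjusted p = 0.125 with an estimated correlation). Its repressor Nfil3 rose by 1.03 ± 0.060. Erythroid markers were 0 up and 4 down of 7 (0 and 5 adjusted over the list alone), with a median of -0.21 but a mean of 0.059 and a test in the downward direction (adjusted p = 0.00864, and adjusted p = 0.0636 with an estimated correlation). The globin Hbb-bs stood at -0.32 ± 0.032. Cholangiocyte markers were 1 up and 0 down of 8 (2 and 0 adjusted over the list alone, median log2 change 0.66, camera adjusted p = 0.0499, and adjusted p = 0.299 with an estimated correlation). The call was lost under quantile normalization and trimmed-mean scaling (adjusted p 0.0361 to 0.0638 over the 4 scalings). Its 1 passing member was Spp1, the secreted protein osteopontin (1.55 ± 0.041). The proteasome list had a median log2 change 0.066, camera adjusted p = 0.0357, and adjusted p = 0.299 with an estimated correlation, although its members were 0 up and 1 down of 23 (0 and 1 adjusted over the list alone). Its call was lost with equal medians and equal totals (adjusted p 0.00850 to 0.181 over the 4 scalings).

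Genes of selenium and redox biology went both ways in β-CYP. NRF2 targets were 5 up and 6 down of 29 (7 and 11 adjusted over the list alone), and genes of selenium handling 0 up and 3 down of 13 (0 and 3 adjusted over the list alone), with camera adjusted p = 0.0731 and fry adjusted p = 1.3e-04. Of the selenoproteins, 3 of the 23 tested members rose and 2 fell (3 and 3 adjusted over the list alone). Msrb1, a methionine sulfoxide reductase, rose by 0.32 ± 0.026 and the thioredoxin reductase Txnrd1 by 0.20 ± 0.042, which did not pass under equal totals (adjusted p = 0.0821, 0.00451 to 0.0821 over the alternatives). The deiodinase Dio1 was at -0.14 ± 0.035 (adjusted p = 0.0247). It no longer passed when any of 5 of the 6 libraries was left out, with adjusted p up to 0.0860, the exception being β-CYP replicate 1. Nor did it pass with equal totals, trimmed-mean scaling or a replicate block (adjusted p 0.0152 to 0.204 over the alternatives). The plasma selenium carrier Selenop (-0.022 ± 0.018, or 0.13 and passing under quantile normalization) and the peroxidases Gpx1 (-0.21 ± 0.69) and Gpx4 (0.012 ± 0.029) did not pass. The standard error of Gpx1 includes the selenite libraries, with 38258, 4241 and 35500 reads, since the fit shares the spread of all groups. Selenbp2, a selenium-binding protein, fell (log2 change -0.52 ± 0.019). The heme oxygenase Hmox1 rose by 0.89 ± 0.071, whereas the quinone reductase Nqo1 (-0.20 ± 0.26) did not pass. Of the drug-metabolizing genes, Cyp2b10, a target of the nuclear receptor CAR, rose 4.56-fold (log2 change 2.19 ± 0.063) and Cyp3a11 by 0.61 ± 0.023, while Alas1, the first enzyme of heme synthesis, was at -1.22 ± 0.047. The CAR and PXR list was 11 up and 7 down of 31 (15 and 8 adjusted over the list alone) and did not pass as a list (adjusted p = 0.0868). Cyp1a2 was at -0.074 ± 0.021 (adjusted p = 0.0386) and did not pass when any 1 of the 6 libraries was left out (adjusted p 0.0521 to 0.116). Nor did it under quantile, total or trimmed-mean scaling, with a replicate block or without the filter on low values (adjusted p 0.00995 to 0.689 over the alternatives). Albumin (Alb) rose by 0.25 ± 0.019. Its change was 0 under quantile normalization, which sets the most abundant gene equal in all libraries. The cell cycle inhibitor Cdkn1a, a p53 target, rose by 3.15 ± 0.43, and the p53 list was 4 up and 2 down of 17 (5 and 3 adjusted over the list alone). The lists that did not pass, with their adjusted p, were periportal hepatocyte genes (0.0582), selenium handling and selenocysteine insertion (0.0731), CAR and PXR responsive genes (0.0868), p53 targets (0.142), pericentral hepatocyte genes (0.286), cell cycle (0.310), sinusoidal endothelium markers (0.399) and oxidative phosphorylation (0.422). Further ones were female-biased liver genes (0.450), pancreatic acinar markers (0.477), AHR responsive genes (0.478), antioxidant enzymes (0.478), lymphocyte markers (0.605), NRF2 target genes (0.849), Kupffer cell and macrophage markers (0.849) and sex chromosome genes (0.850). With the highest adjusted p came skeletal muscle markers (0.917), amino acid and urea metabolism (0.923), adipocyte markers (0.923), voltage-gated sodium channels and nerve markers (0.928), apoptosis regulators (0.931) and selenoproteins (0.981). With equal medians, selenium handling and periportal genes passed downward (adjusted p 0.0397 to 0.182 and 0.0307 to 0.182 over the 4 scalings). The median, the mean and the test did not all share a sign in 9 of these 22 lists. These were selenoproteins, NRF2 targets, antioxidant enzymes, AHR genes, pancreas, muscle, sex chromosome, amino acid, and nerve genes. For pancreas and muscle the median was 0, and the mean and the test had the same sign.

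The largest rises in β-CYP were those of Dmbt1, a mucosal scavenger protein (log2 change 6.56 ± 0.30), Timp1, Mid1-ps1, Lypd8, Mir686, Gdpd3, Atp6v0a4 and AC147560.1. Lypd8 had 0 reads in control and was at least 15.2-fold higher, and Mid1-ps1, with 2 control reads, was higher 138-fold (95% counting interval 36.4 to 1102). The call of Mid1-ps1 was lost with a pseudocount of 0.01 (adjusted p = 0.0595, 0.00129 to 0.0595 over the alternatives). Mir686 rose by 5.47 ± 0.25, Gdpd3 by 5.37 ± 0.69 and Atp6v0a4 by 5.01 ± 0.58. AC147560.1 (4.79 ± 1.14) did not pass when any 1 of the 6 libraries was left out, with adjusted p of 0.0522 to 0.0665. It had 2, 1 and 2 reads in control and 75, 66 and 83 in β-CYP. In selenite it had 1, 1 and 63, and these libraries also enter its standard error through the shared fit. Of the 8 largest falls, 5 were transcripts of the testis or spermatids: Prm2 (-5.50 ± 0.69), Tnp1, Smcp, Akap4 and Gsg1. The last 4 had 0 reads in β-CYP and were at least 17.1-fold, 11.9-fold, 11.2-fold and 10.2-fold lower. A list of spermatid transcripts, chosen after this was seen, summed to 316 to 364 reads in the control libraries, 12 to 23 in β-CYP and 11 to 24 in selenite. The other falls were those of Cebpe, a transcription factor of granulocytes, and the pseudogene H2-Ea-ps, with 202 and 171 reads in control and 0 in β-CYP (Cebpe at least 23.8-fold lower), and of Igsf23, which had 446 reads in control and 3 in β-CYP, a ratio of 0.00669 (95% counting interval 0.00131 to 0.0187).

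**Figure D2:**
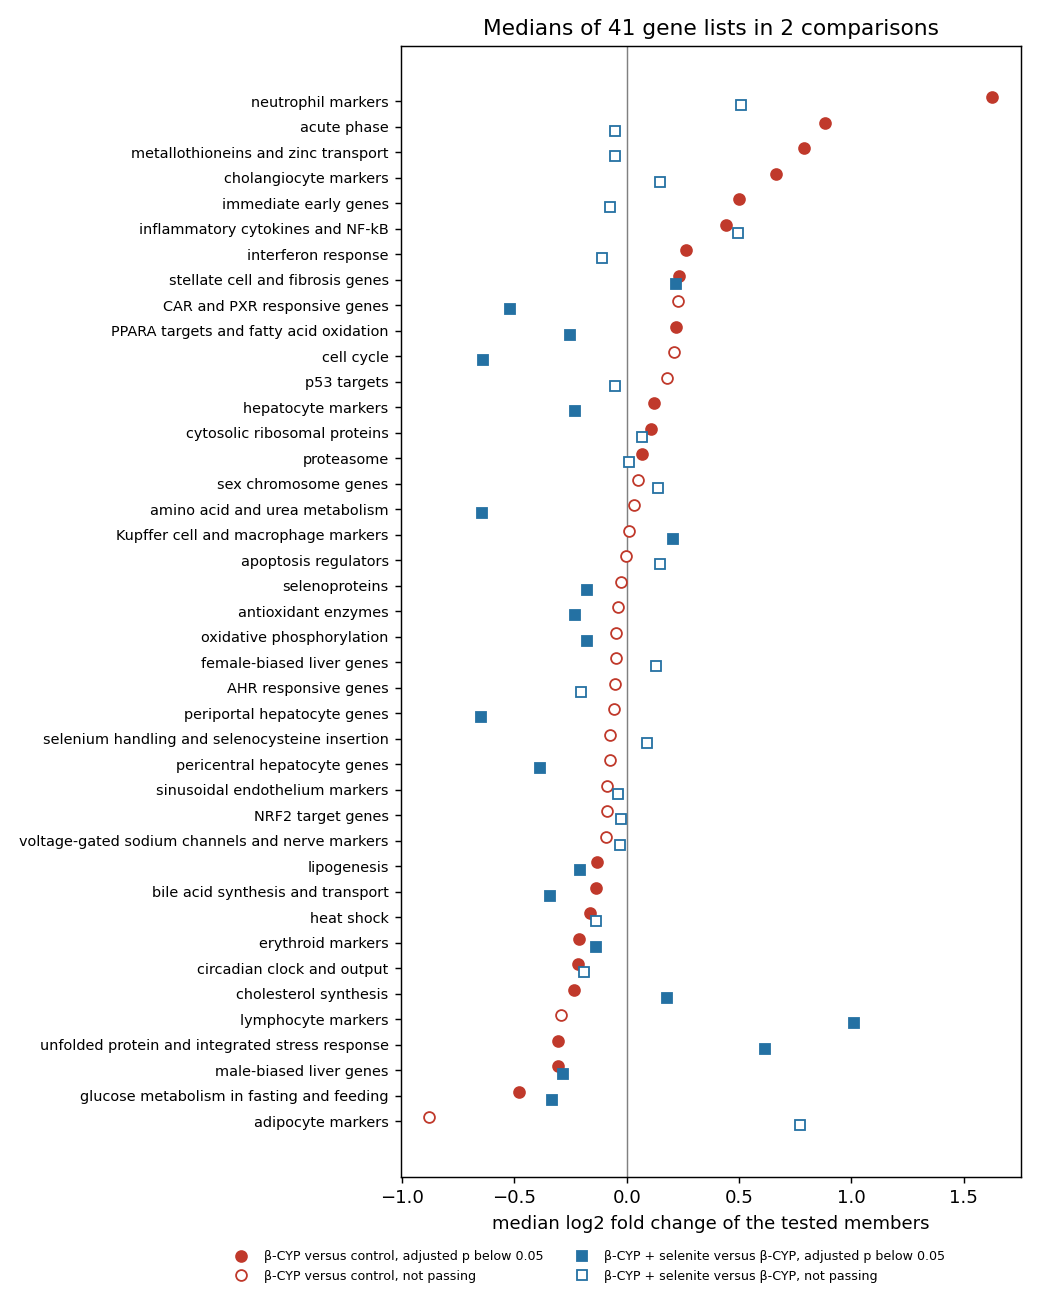
Median log2 fold change of the tested members of each gene list, in β-CYP against control (circles) and in selenite against β-CYP (squares), with filled symbols for camera adjusted p below 0.05; pancreas and muscle lists are left out for scale. Cholesterol synthesis and the unfolded protein list lay below 0 in the first comparison and above 0 in the second, and the list of PPARA targets and fatty acid oxidation the other way round.

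The second comparison, selenite with β-CYP, asks what changes when selenite is added. Enzymes of amino acid breakdown and the urea cycle fell together. Tat, which degrades tyrosine, went from 58171 ± 195 to 22089 ± 279 scaled counts (mean ± SD, n = 3, limma adjusted p = 5.7e-11), and 23 of 24 genes of that list fell. Hepatocyte markers fell as well, 13 of 18 (median log2 change -0.23, camera adjusted p = 3.6e-08), although not as a list with an estimated correlation (adjusted p = 0.122) or under quantile normalization (adjusted p 2.4e-09 to 0.0849 over the 4 scalings). Genes of the unfolded protein and integrated stress list, most of them low in β-CYP, were mostly higher with selenite, 20 up and 2 down of 25. Among them, Creld2 went from 1333 ± 84.2 to 6079 ± 220 (adjusted p = 2.5e-09). Cd163, the hemoglobin scavenger receptor of macrophages, rose 6.04-fold, and Cyp2b10 fell from 2457 ± 94.2 to 559 ± 25.5. Macrophage and lymphocyte markers rose as lists, by smaller median log2 changes of 0.21 and 1.01, with 10 of 16 and 5 of 17 members up. The selenite libraries also held 41372 to 42380 reads of pancreatic markers, against 977 to 1254 in the other libraries. In limma's test 4805 of 20145 genes passed (23.9%), 2337 higher and 2468 lower, of which 690 and 437 differed at least 2-fold. Groups did not overlap for 7613 genes (37.8%, against 10% by chance), including 4786 of those that passed and all 67 that passed among the 74 named for this comparison. The split into higher and lower depends on the scaling: it was 1532 and 3852 with equal medians, 3238 and 1334 with equal totals, and 3170 and 1874 with trimmed-mean scaling. The median log2 change of all genes, 0.017 here, was -0.096, 0.14 and 0.096 under these, and -0.018 under quantile normalization.

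Of the amino acid and urea list, 0 of the 24 tested members rose and 23 fell (0 and 24 adjusted over the list alone, median log2 change -0.65, camera adjusted p = 5.7e-28). The aminotransferase Got1 (-1.89 ± 0.13) and the urea cycle enzymes Asl (-1.01 ± 0.049), Ass1 (-0.83 ± 0.020) and Arg1 (-0.66 ± 0.019) were examples. Periportal hepatocyte genes, which share Ass1, Asl and Arg1 with that list, were 0 up and 12 down of 13 (0 and 12 adjusted over the list alone, median log2 change -0.65, camera adjusted p = 1.3e-12), and pericentral genes 1 up and 7 down of 13 (1 and 8 adjusted over the list alone, median log2 change -0.38, camera adjusted p = 4.2e-05). The pericentral oxidase Cyp1a2 was at -0.62 ± 0.021. CAR and PXR responsive genes were 1 up and 18 down of 31 (1 and 18 adjusted over the list alone, median log2 change -0.52, camera adjusted p = 2.5e-11): Cyp2b10 (-2.13 ± 0.063), Cyp2a5 (-1.94 ± 0.036) and the carboxylesterase Ces2a (-1.53 ± 0.041) fell, and Cyp3a11 did not pass (-0.048 ± 0.023). It did without β-CYP replicate 1 (adjusted p = 0.0244), with equal medians at -0.18 and, upward, with quantile normalization at 0.19. The PPARA and fatty acid oxidation list was 4 up and 19 down of 32 (5 and 21 adjusted over the list alone, median log2 change -0.25, camera adjusted p = 2.9e-07). The fatty acid hydroxylases Cyp4a14 (-4.18 ± 0.36) and Cyp4a10 (-2.86 ± 0.10) fell. Bile acid genes were 2 up and 15 down of 19 (2 and 16 adjusted over the list alone, median log2 change -0.34, camera adjusted p = 6.3e-09). The sterol exporter Abcg8 (-0.89 ± 0.049) and the reductase Akr1d1 (-0.79 ± 0.048) fell, Cyp7b1 rose by 0.78 ± 0.028, and Cyp7a1 did not pass (-0.057 ± 0.067). Cholesterol synthesis went up, with 15 up and 5 down of 24 (15 and 6 adjusted over the list alone, median log2 change 0.18, camera adjusted p = 9.0e-04), through Mvd (1.02 ± 0.089), the isomerase Idi1 (0.73 ± 0.095) and the epoxidase Sqle (0.68 ± 0.055). Oxidative phosphorylation was 0 up and 15 down of 26 (0 and 16 adjusted over the list alone, median log2 change -0.18, camera adjusted p = 6.8e-07), a call lost under quantile normalization (adjusted p 2.8e-09 to 0.24 over the 4 scalings). Cell cycle genes were 1 up and 6 down of 24 (1 and 6 adjusted over the list alone, median log2 change -0.64, camera adjusted p = 0.00439). The replication helicase subunit Mcm5 was at -1.31 ± 0.20 and the proliferation marker Mki67 at -0.98 ± 0.16.

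The unfolded protein and integrated stress list rose, 20 up and 2 down of 25 (21 and 2 adjusted over the list alone, median log2 change 0.62, camera adjusted p = 4.2e-13), with Creld2 (2.19 ± 0.050), Hyou1 (1.48 ± 0.035), Hspa5 (1.15 ± 0.13) and the stress transcription factor Atf3 (1.43 ± 0.29) up and Chac1 down 2.30-fold. Heat shock genes moved both ways, 5 up and 6 down of 15 (6 and 8 adjusted over the list alone), and did not pass as a list (adjusted p = 0.905). The small chaperone Hspb1 (2.76 ± 0.078) and Hspa1a (2.14 ± 0.087) rose and the constitutive Hspa8 fell (-1.46 ± 0.069). Kupffer cell and macrophage markers were 10 up and 0 down of 16 (11 and 0 adjusted over the list alone, median log2 change 0.21, camera adjusted p = 2.9e-06). Besides Cd163, the scavenger receptor Marco rose by 2.02 ± 0.12 and the integrin Itgam by 2.11 ± 0.46. Lymphocyte markers were 5 up and 0 down of 17 (6 and 0 adjusted over the list alone, median log2 change 1.01, camera adjusted p = 0.00140). The selenite libraries, in which these immune markers were higher, are also those with pancreatic and muscle transcripts (41372 to 42380 and 910 to 986 reads). Stellate cell genes were 7 up and 1 down of 18 (9 and 2 adjusted over the list alone, median log2 change 0.22, camera adjusted p = 0.0127, and adjusted p = 0.0636 with an estimated correlation), with the basement membrane collagen Col4a1 (0.71 ± 0.084) and vimentin (Vim, 0.87 ± 0.11) up. The call was lost with equal medians (adjusted p 0.00474 to 0.0546 over the 4 scalings). The acute phase list went both ways, 11 up and 12 down of 26 (11 and 12 adjusted over the list alone), and did not pass (adjusted p = 0.563). Saa1 (-0.75 ± 0.027) and Lcn2 (-0.74 ± 0.060) fell and the endotoxin co-receptor Cd14 rose by 1.75 ± 0.11. Cxcl1 fell (log2 change -1.47 ± 0.043), while the inflammatory list, 6 up and 4 down of 21 (9 and 4 adjusted over the list alone), did not pass (adjusted p = 0.273).

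Selenoprotein transcripts were on balance lower with selenite: 3 of the 23 tested members rose and 9 fell (5 and 9 adjusted over the list alone, median log2 change -0.18, camera adjusted p = 0.0274, and adjusted p = 0.111 with an estimated correlation). The call was lost with quantile normalization, equal totals and trimmed-mean scaling (adjusted p 0.0217 to 0.231 over the 4 scalings). Msrb1 (-0.70 ± 0.026), Selenow, a small thioredoxin-like selenoprotein (-0.59 ± 0.035), and Gpx4 (-0.24 ± 0.029, lost with equal totals, adjusted p 1.8e-05 to 0.179 over the alternatives) fell. Selenon (0.94 ± 0.17), Selenok (0.52 ± 0.059) and Selenos (0.38 ± 0.056), proteins of the endoplasmic reticulum, rose. Dio1 was at -0.30 ± 0.035, lost with equal totals (adjusted p 2.4e-05 to 0.0538 over the alternatives). Txnrd1 was at -0.18 ± 0.042 (adjusted p = 0.0134), and did not pass without β-CYP replicate 3 (0.0501) or under quantile, total or trimmed-mean scaling (adjusted p 2.8e-04 to 0.673 over the alternatives). Selenop did not pass (-0.040 ± 0.018) but did with equal medians, at -0.17. Gpx1 did not pass (-1.25 ± 0.69, or -0.20 without selenite replicate 2); it had 38258, 4241 and 35500 reads in selenite replicates 1, 2 and 3. Selenbp2 rose 2.51-fold (1.33 ± 0.019). Mt1 (0.0038 ± 0.018), Hmox1 (0.011 ± 0.071) and Nqo1 (-0.34 ± 0.26) did not pass. Mt1 passed upward under quantile normalization, at 0.33, and trimmed-mean scaling, at 0.085, and downward with equal medians, at -0.13. Antioxidant enzymes were 1 up and 9 down of 20 (1 and 10 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 5.4e-04, and adjusted p = 0.0978 with an estimated correlation), with catalase (Cat, -0.55 ± 0.018) and the peroxiredoxin Prdx6 (-0.57 ± 0.089) down. The call was lost under quantile normalization (adjusted p 5.4e-05 to 0.279 over the 4 scalings).

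The other lists that passed lost their call with an estimated correlation. Hepatocyte markers were 1 up and 13 down of 18 (1 and 15 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 3.6e-08, and adjusted p = 0.122 with an estimated correlation), including the transcription factor Hnf4a (-0.66 ± 0.027). Alb was at -0.38 ± 0.019, or 0 under quantile normalization, where the list did not pass either (adjusted p 2.4e-09 to 0.0849 over the 4 scalings). Male-biased genes were 3 up and 10 down of 19 (4 and 11 adjusted over the list alone, median log2 change -0.28, camera adjusted p = 9.6e-04, and adjusted p = 0.0636 with an estimated correlation, lost also under quantile normalization, adjusted p 2.3e-04 to 0.622 over the 4 scalings). The fatty acid elongase Elovl3 fell (-2.38 ± 0.033) and the urinary protein gene Mup21 rose (2.51 ± 0.052). Lipogenesis was 2 up and 8 down of 19 (4 and 8 adjusted over the list alone, median log2 change -0.21, camera adjusted p = 0.00759), with a median of 0.023 under quantile normalization, where it did not pass, nor with equal totals (adjusted p 2.3e-04 to 0.693 over the 4 scalings). It gave adjusted p = 0.120 with an estimated correlation. Glucose metabolism was 3 up and 7 down of 15 (3 and 8 adjusted over the list alone, median log2 change -0.33, camera adjusted p = 0.00705, adjusted p = 0.129 with an estimated correlation, lost also under quantile normalization, adjusted p 3.7e-04 to 0.284 over the 4 scalings). Erythroid markers were 0 up and 2 down of 7 (0 and 4 adjusted over the list alone, median log2 change -0.14, camera adjusted p = 0.0103, and adjusted p = 0.0661 with an estimated correlation), lost under quantile, total and trimmed-mean scaling (adjusted p 0.00401 to 0.463 over the 4 scalings). Lists that did not pass, with their adjusted p, were circadian clock and output (0.0551), NRF2 target genes (0.0697), immediate early genes (0.0731), neutrophil markers (0.109), AHR responsive genes (0.133), metallothioneins and zinc transport (0.209) and cytosolic ribosomal proteins (0.267). The remaining ones were inflammatory cytokines and NF-kB (0.273), sex chromosome genes (0.298), p53 targets (0.298), apoptosis regulators (0.356), adipocyte markers (0.478), cholangiocyte markers (0.483) and selenium handling and selenocysteine insertion (0.535). With the highest adjusted p came acute phase (0.563), interferon response (0.766), heat shock (0.905), sinusoidal endothelium markers (0.928), voltage-gated sodium channels and nerve markers (0.928), proteasome (0.969) and female-biased liver genes (0.981). Other scalings brought calls among these. Ribosomal proteins passed upward under quantile, total and trimmed-mean scaling and downward with equal medians (adjusted p 4.5e-06 to 0.0491 over the 4 scalings). With equal medians, NRF2 targets (adjusted p 0.0180 to 0.933 over the 4 scalings), the circadian list (0.0295 to 0.127), metallothioneins (0.0397 to 0.684) and the proteasome (0.00401 to 0.110) passed downward and neutrophil markers (0.0402 to 0.209) upward. The signs of median, mean and test differed in 10 of these 21 lists: selenium handling, NRF2 targets, metallothioneins, heat shock, sinusoidal endothelium, cholangiocytes, female-biased genes, ribosomal proteins, proteasome and nerve genes.

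All 8 of the largest rises were digestive enzymes of the exocrine pancreas. Pancreatic lipase (Pnlip), the proteases Prss2, Cpa1 and Try4 and the amylases Amy2a2, Amy2a3 and Amy2a4 had 0 reads in β-CYP and 5258 ± 191, 2397 ± 85, 2464 ± 29, 3607 ± 224, 4629 ± 67, 4447 ± 79 and 4470 ± 79 scaled counts in selenite (mean ± SD, n = 3). Pnlip was at least 1761-fold higher. Amy2a5 had 3 reads in β-CYP and was higher 4619-fold (95% counting interval 1574 to 22314). Together the 12 pancreatic markers took 41372 to 42380 reads (0.126% to 0.129%) in the selenite libraries and 977 to 1254 (0.00273% to 0.0037%) in the other 6, where most were of Cela1. All 12 rose, and 12 did adjusted over the list alone (camera adjusted p = 4.1e-19). Skeletal muscle markers took 910 to 986 reads in selenite against 12 to 27 elsewhere, and 7 of the 7 tested rose, as adjusted over the list alone (adjusted p = 3.1e-08). Creatine kinase (Ckm) had 0 reads in β-CYP and was at least 40.3-fold higher. The largest falls were those of Mup-ps19 and Mup13, with 61277 and 40013 reads in β-CYP and 0 in selenite (at least 7216-fold and 4741-fold lower). These belong to the family of major urinary proteins, whose copies share reads. Cyp4a14, the translation termination factor Gspt2 (-4.56 ± 0.28), Mid1-ps1 (-5.02 ± 1.11), AC166078.1 (-4.22 ± 0.61), AC153370.2 and the immunoglobulin segment Ighv6-3 followed, the last 2 without reads in selenite (at least 12.0-fold and 5.33-fold lower). Mid1-ps1 had 0, 25 and 0 reads in selenite replicates 1, 2 and 3, and lost its call with a pseudocount of 0.01 and in a fit of the 2 groups alone (adjusted p 1.1e-04 to 0.0701 over the alternatives).

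**Figure D3:**
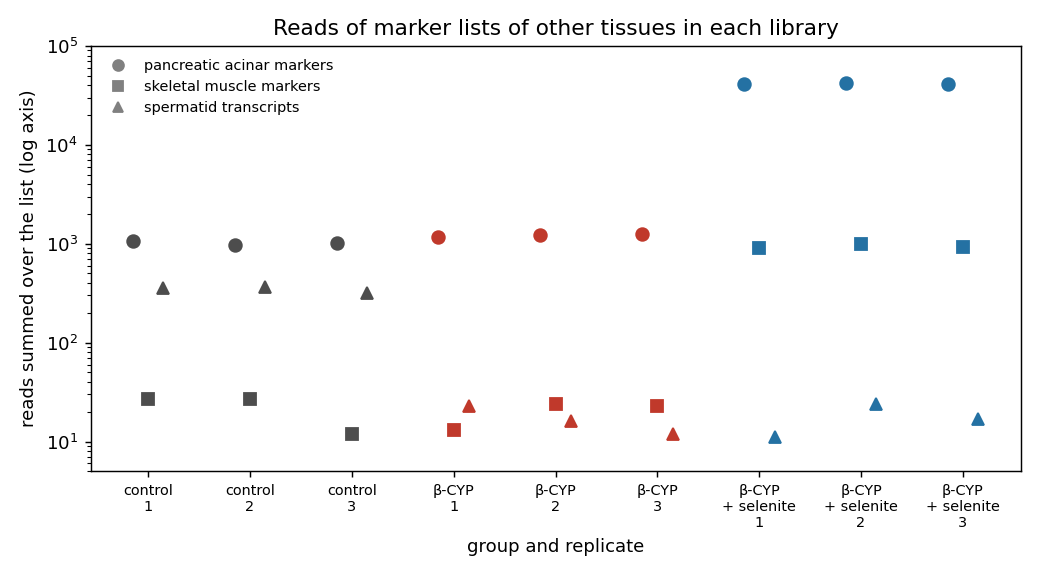
Reads summed over marker lists of exocrine pancreas, skeletal muscle and spermatids in each library, on a log axis. Pancreas and muscle sums were highest in the 3 libraries given β-CYP with selenite, at 41372 to 42380 and 910 to 986 reads, and spermatid sums in the 3 controls, at 316 to 364.

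The third comparison, selenite with control, asks what differs from untreated liver when both compounds are given. Acute phase and neutrophil transcripts were higher than in control: Saa1 stood at 170134 ± 4870 against 45628 ± 1008 scaled counts (mean ± SD, n = 3, adjusted p = 5.3e-11), and S100a8 rose 8.86-fold (adjusted p = 1.0e-05). Cyp7a1, at 850 ± 76.8 against 4844 ± 120 (adjusted p = 3.4e-09), G6pc (8.39-fold lower) and Tat (3.67-fold lower) were below control. In limma's test 5823 of 20145 genes passed (28.9%), 2908 higher and 2915 lower, of which 894 and 679 differed at least 2-fold. Groups did not overlap for 8418 genes (41.8%, against 10% by chance), including 5779 of those that passed and all 57 that passed among the 61 named for this comparison. The split was 1827 and 4539 with equal medians, 3977 and 1763 with equal totals, and 3988 and 2173 with trimmed-mean scaling. The median log2 change of all genes, 0.027 here, was -0.12, 0.16 and 0.12 under these.

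The acute phase list was 24 up and 1 down of 26 (24 and 1 adjusted over the list alone, median log2 change 1.12, camera adjusted p = 2.3e-27). Saa2 was at 2.80 ± 0.027, Serpina3n at 2.37 ± 0.017, Lcn2 at 2.51 ± 0.060 and Cd14 at 2.33 ± 0.11. Metallothioneins and zinc transport were 4 up and 1 down of 7 (4 and 1 adjusted over the list alone, median log2 change 1.04, camera adjusted p = 6.2e-04). Mt1 was at 2.38 ± 0.018 and Mt2 at 1.94 ± 0.022. Neutrophil markers were 8 up and 0 down of 10 (9 and 0 adjusted over the list alone, median log2 change 2.97, camera adjusted p = 6.6e-05). S100a9 was at 2.89 ± 0.23. Inflammatory cytokines were 10 up and 1 down of 21 (11 and 1 adjusted over the list alone, median log2 change 1.19, camera adjusted p = 6.2e-05). Macrophage markers were 11 up and 0 down of 16 (12 and 0 adjusted over the list alone, median log2 change 0.42, camera adjusted p = 4.1e-06). The monocyte receptor Ccr2 was at 2.14 ± 0.25 and Cd163 at 1.03 ± 0.074. The selenite libraries compared here are those with pancreatic and muscle transcripts (41372 to 42380 and 910 to 986 reads). Stellate cell genes were 12 up and 0 down of 18 (13 and 1 adjusted over the list alone, median log2 change 0.46, camera adjusted p = 9.2e-06). Timp1 was at least 13.5-fold higher and Vim at 1.35 ± 0.11. Interferon response genes were 10 up and 3 down of 26 (10 and 4 adjusted over the list alone, median log2 change 0.19, camera adjusted p = 0.0482, and adjusted p = 0.104 with an estimated correlation), lost with quantile normalization and equal medians (adjusted p 0.0431 to 0.103 over the 4 scalings). Lymphocyte markers were 4 up and 0 down of 17 (4 and 0 adjusted over the list alone, median log2 change 0.72, camera adjusted p = 0.0236, and adjusted p = 0.0826 with an estimated correlation), lost with equal totals and trimmed-mean scaling (adjusted p 0.00318 to 0.0723 over the 4 scalings). The unfolded protein list was 14 up and 3 down of 25 (14 and 3 adjusted over the list alone, median log2 change 0.16, camera adjusted p = 8.4e-05). Creld2 was at 0.75 ± 0.050 and Atf3 at 2.68 ± 0.29. Hspb1 rose by 2.71 ± 0.078.

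Amino acid and urea genes were 2 up and 21 down of 24 (2 and 21 adjusted over the list alone, median log2 change -0.58, camera adjusted p = 4.1e-19). Got1 was at -2.49 ± 0.13. Periportal genes were 1 up and 11 down of 13 (1 and 11 adjusted over the list alone, median log2 change -0.59, camera adjusted p = 8.5e-12). The lyase Etnppl was at -3.32 ± 0.083. Pericentral genes were 1 up and 9 down of 13 (1 and 9 adjusted over the list alone, median log2 change -0.40, camera adjusted p = 2.4e-05), with Cyp1a2 at -0.69 ± 0.021. Bile acid genes were 2 up and 16 down of 19 (2 and 16 adjusted over the list alone, median log2 change -0.51, camera adjusted p = 4.2e-13), with the organic anion transporter Slco1a1 at -1.26 ± 0.032. Glucose metabolism was 2 up and 12 down of 15 (2 and 12 adjusted over the list alone, median log2 change -0.62, camera adjusted p = 2.1e-08), and lipogenesis 3 up and 9 down of 19 (3 and 9 adjusted over the list alone, median log2 change -0.39, camera adjusted p = 8.4e-05), with the desaturase Fads2 at -0.98 ± 0.028. Male-biased genes were 2 up and 16 down of 19 (2 and 17 adjusted over the list alone, median log2 change -0.91, camera adjusted p = 1.3e-11). Mup7 was at -1.87 ± 0.063 and Hsd3b5 at -1.68 ± 0.040. The circadian list was 0 up and 10 down of 18 (0 and 10 adjusted over the list alone, median log2 change -0.29, camera adjusted p = 5.6e-05). The clock repressors Per1 (-0.92 ± 0.092) and Nr1d1 (-0.65 ± 0.034) fell. Erythroid markers were 0 up and 5 down of 7 (0 and 5 adjusted over the list alone, median log2 change -0.39, camera adjusted p = 5.7e-04). Oxidative phosphorylation was 0 up and 17 down of 26 (0 and 17 adjusted over the list alone, median log2 change -0.20, camera adjusted p = 3.8e-07), lost under quantile normalization (adjusted p 2.6e-09 to 0.244 over the 4 scalings).

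The CAR and PXR list was 4 up and 15 down of 31 (5 and 15 adjusted over the list alone), with a median of -0.0060 that became 0.11 with equal totals and 0.075 with trimmed-mean scaling, while its test stayed downward (camera adjusted p = 3.8e-04). Cyp2a5 (-2.59 ± 0.036) and Alas1 (-2.40 ± 0.047) fell, Cyp3a11 rose by 0.56 ± 0.023, and Cyp2b10 did not pass (0.053 ± 0.063) but did with equal totals, at 0.19 (adjusted p = 0.0490, 0.0490 to 0.889 over the alternatives). Ribosomal proteins were 11 up and 2 down of 24 (16 and 2 adjusted over the list alone, median log2 change 0.12, camera adjusted p = 6.2e-05), with a median of -0.047 under equal medians, where they did not pass (adjusted p 6.4e-10 to 0.348 over the 4 scalings), and adjusted p = 0.120 with an estimated correlation. Hepatocyte markers were 4 up and 10 down of 18 (5 and 10 adjusted over the list alone, median log2 change -0.13, camera adjusted p = 0.0445), with a median of 0.0022 under equal totals, and passed neither with an estimated correlation (adjusted p = 0.524) nor with quantile, total or trimmed-mean scaling (adjusted p 5.6e-04 to 0.990 over the 4 scalings). Alb was at -0.13 ± 0.019 but at 0.0042 with equal totals and 0 under quantile normalization. Selenoproteins were 4 up and 9 down of 23 (4 and 9 adjusted over the list alone, median log2 change -0.22, camera adjusted p = 0.0357, and adjusted p = 0.120 with an estimated correlation), lost with quantile, total and trimmed-mean scaling (adjusted p 0.0114 to 0.631 over the 4 scalings). Selenow (-0.68 ± 0.035) and Dio1 (-0.44 ± 0.035) fell, as did Gpx4 (-0.23 ± 0.029, lost with equal totals, adjusted p 1.0e-05 to 0.252 over the alternatives), and Selenon rose by 1.27 ± 0.17. Selenop was at -0.063 ± 0.018 (adjusted p = 0.0262), but at 0.10 under quantile normalization, 0.074 with equal totals and 0.040 with trimmed-mean scaling. The first of these passed, so the call turned upward there (adjusted p = 0.0154, 1.9e-05 to 0.321 over the alternatives). It did not pass without control replicate 2 or 3 or selenite replicate 1 or 2, with adjusted p up to 0.0946. Gpx1 did not pass (-1.45 ± 0.69) but did, at a log2 change of -0.41 (adjusted p = 0.0223, 0.0223 to 0.279 over the alternatives), without selenite replicate 2. Txnrd1 (0.021 ± 0.042) and Nqo1 (-0.54 ± 0.26) did not pass, Nqo1 doing so without control replicate 1 (adjusted p = 0.0247, 0.0247 to 0.451 over the alternatives), Txnrd1 under quantile normalization at 0.12 and with equal medians at -0.14. Hmox1 (0.90 ± 0.071) and Selenbp2 (0.81 ± 0.019) rose. Antioxidant enzymes were 1 up and 11 down of 20 (1 and 12 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 6.2e-04, and adjusted p = 0.101 with an estimated correlation, lost also under quantile normalization, adjusted p 1.2e-04 to 0.247 over the 4 scalings), with Cat at -0.73 ± 0.018. All 12 pancreas markers (adjusted p = 9.2e-17) and all 7 tested muscle markers (adjusted p = 3.8e-07) rose, with the same numbers adjusted over the list alone. The 8 largest rises were those of the pancreas genes Pnlip, Amy2a2, Amy2a3, Amy2a4, Amy2a5, Try4 and Cpa1, with 0 control reads, and Ctrb1 (11.27 ± 0.78). Pnlip was at least 1663-fold and Ckm at least 38.1-fold higher. Among the falls, Mup13, Mup-ps19, Cyp2c40, Prm2, Tnp1, Prm1 and Tnp2 had 0 reads in selenite (at least 7106-fold, 6945-fold, 186-fold, 29.9-fold, 18.2-fold, 16.3-fold and 12.5-fold lower). Cebpe was at -5.20 ± 0.73. Cyp2c40, 521 ± 432 in control, did not pass when any of 5 of the 6 libraries was left out, with adjusted p up to 0.0993, the exception being control replicate 2. It did not pass with voom, with a replicate block or with robust eBayes either (adjusted p 0.00702 to 0.517 over the alternatives). Lists that did not pass, with their adjusted p, were cell cycle (0.0627), proteasome (0.140), selenium handling and selenocysteine insertion (0.142), AHR responsive genes (0.195), immediate early genes (0.232) and PPARA targets and fatty acid oxidation (0.298). Others were sex chromosome genes (0.348), NRF2 target genes (0.348), adipocyte markers (0.422), p53 targets (0.440), heat shock (0.455) and apoptosis regulators (0.478). With the highest adjusted p came female-biased liver genes (0.681), cholesterol synthesis (0.754), cholangiocyte markers (0.835), sinusoidal endothelium markers (0.850) and voltage-gated sodium channels and nerve markers (0.981). Cell cycle genes passed downward (adjusted p 0.0175 to 0.138 over the 4 scalings) and the proteasome upward (5.7e-04 to 0.0566) under quantile, total and trimmed-mean scaling, and the PPARA list downward with equal medians (0.0136 to 0.992). Median, mean and test differed in sign in 5 of these 17: NRF2 targets, AHR genes, sinusoidal endothelium, female-biased genes and sex chromosome genes.

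The repair question was addressed by asking which changes of β-CYP were followed by a change in the opposite direction when selenite was added. Of the 3285 genes that changed in β-CYP, 1208 then passed in the opposite direction. This need not be a return to control: 193 genes were higher than control in β-CYP and lower than control in selenite, and 127 the reverse. In selenite against control, the unfolded protein list was 14 up and 3 down, the PPARA list 7 and 12, and hepatocyte markers 4 and 10. Cholesterol synthesis was 8 up and 8 down. The counts by list below were not tested against other genes. The selenite libraries are also those with pancreatic and muscle transcripts (41372 to 42380 and 910 to 986 reads), whose part in these counts was not tested. Of the 21 genes of the unfolded protein list that changed in β-CYP, 16 fell and then rose, and of the 16 cholesterol synthesis genes 10 did, including Mvd. Of the 21 genes of the PPARA and fatty acid oxidation list that changed, 14 rose and then fell, as did 9 of 18 CAR and PXR genes, Cyp2b10 among them, and 8 of 11 hepatocyte markers. Acute phase genes went both ways: of 24 that changed, 12 rose and then fell, including Saa1 and Lcn2, 9 moved further in the same direction, and 22 were higher than control in both treated groups. Bile acid and glucose genes mostly stayed low, with 9 of 12 and 11 of 14 that had changed in β-CYP below control in both treated groups, including Cyp7a1 and G6pc. Of the 1208 genes in opposite directions, 633 rose and then fell, against 190.6 for independent lists, and 575 fell and then rose, against 200.6. In the same direction, 189 rose in both, against 180.5, and 389 fell in both, against 211.8. Both comparisons use the β-CYP libraries, and in 50 simulated sets with no group changed 0 genes passed in opposite directions, with at most 1 when selenite equalled β-CYP. In these sets means of only 0.1 and 0.12 genes passed in selenite against β-CYP, so hardly any overlap was possible. Unrelated changes in both comparisons were not simulated, so the part due to the shared libraries is not known. When selenite was simulated at the control level, 3860 to 4041 genes passed in opposite directions, of a mean of 4997 that passed in the first comparison there, against 3285 in the data. Higher than control in both treated groups were 883 genes, against 224.6 for independent lists, and lower in both 1079, against 250.2. These comparisons share the controls, so part of the excess may come from them. Simulation with no change gave at most 1, but means of only 0.08 and 0.22 genes passed in the 2 comparisons there, so it does not measure that part. To measure how much of the change remained, genes were chosen at an unadjusted p below 0.01 without 1 control and 1 β-CYP library, and measured in those that were left out. Over the 9 choices of 2208 to 2338 genes, 86.3% ± 2.04 (SD) of the median change in β-CYP was present in selenite, from 82.5% to 88.3%. The choices re-use the same libraries, so this SD is not a spread between replicates. Both changes were measured from the same left-out control. If the controls came from 1 RNA sample or pool, a deviation they share would count as change that remained. A share of medians also does not describe single genes, of which 1208 reversed direction.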

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

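The alternatives with voom, a minimum mean of 10, a fold of at least 2 and without the genes seen in the selenite group alone were chosen only after the results were seen. Of the 4178 values of named genes under 24 alternatives, 4093 kept direction and side of the threshold, 53 no longer passed, 9 newly passed and 23 changed sign. Of genes that had passed, 2 changed sign, both in selenite against control: Alb (log2 change 0.0042 with equal totals) and Selenop (0.10 with quantile normalization, 0.074 with equal totals, 0.040 with the trimmed mean). Selenop passed with the new sign under quantile normalization. The other sign changes were in genes that had not passed. Of these, 4 passed with the new sign: Selenop in β-CYP against control (0.13) and Cyp3a11 in selenite against β-CYP (0.19) with quantile normalization, and with equal medians Mt1 in selenite against β-CYP (-0.13) and Txnrd1 in selenite against control (-0.14). The rest did not pass with the new sign. With equal medians, Gpx4 in β-CYP against control was at -0.019, Hmox1 in selenite against β-CYP at -0.12 and Cyp2b10 in selenite against control at -0.11. In selenite against β-CYP, equal totals and the trimmed mean gave 0.079 and 0.033 for Cyp3a11, 0.069 and 0.023 for Cyp7a1, and 0.086 and 0.040 for Selenop. Leaving out 1 library gave -0.011 to 0.028 for Gpx4 and -0.48 to 0.044 for Nqo1 in β-CYP against control, and -6.4e-04 to 0.0085 for Mt1 and -0.024 to 0.037 for Hmox1 in selenite against β-CYP. The causes of the sign changes were not tested. With an estimated correlation 13 lists passed in β-CYP against control and 14 in selenite against β-CYP. Fry, which does not compare a list with other genes, gave 36 in the latter. Requiring a 2-fold change left 773, 1127 and 1573 genes in the 3 comparisons, fewer by construction. The share of the change present in selenite was 88.6% with a pseudocount of 0.1, 82.1% with a minimum mean of 5 and 82.9% with quantile normalization. The cause was not tested. Leaving out 1 library gave 2668 to 2833, 3989 to 4123 and 4994 to 5163 genes, 19 to 21, 22 to 23 and 24 to 26 lists, and 981 to 1103 genes in opposite directions. Of the genes called with all libraries, 2483 to 2589, 3770 to 3853 and 4728 to 4816 were called again, 0 with another sign. With the replicate number as a block, counts were 2956, 4481 and 5506 genes, 21, 22 and 25 lists and 1087 opposite genes. Libraries of the same number had correlations of -0.011 to 0.032 over 9 pairs after group means were removed, and matched best with their own number in 11 of 18 cases. Voom gave 3247, 4924 and 5840 genes. Without the 429 genes seen in selenite alone there were 3296, 4667 and 5702. Over the alternatives in which they were counted, genes in opposite directions ran from 909 with equal totals to 1295 with a minimum mean of 10. Fits of only the 2 groups compared gave 1026. The count models DESeq2 and edgeR, fixed beforehand as alternatives, were not run, and edgeR had also been set as the main test for a table of counts. At 10 to 100 scaled counts the median coefficient of variation within a group was 22.9% to 25.2%, against 13.9% to 14.7% from counting.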

Other observations

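The tests of the pancreatic sums between libraries, of the ratio of muscle to pancreatic sums and of the interferon list were chosen only after the results were seen.

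A few genes differed widely between libraries of 1 group. Of 4004 genes with a mean of at least 1000 scaled counts in 1 or more groups, 29 had in such a group a library at least 3-fold away from both others, in 34 cases. Some had high and low libraries in more than 1 group. Retreg3, a receptor of endoplasmic reticulum turnover, had 755, 799 and 2557 reads in control, 633, 2812 and 3116 in β-CYP and 3110, 2856 and 756 in selenite. Usf3, a transcription factor, had 2119, 127 and 1813 in control and 135, 1759 and 2020 in β-CYP. Cyp2c40, below that mean, had 771, 22 and 665 in control, 0, 464 and 0 in β-CYP and 0 in all selenite libraries.

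Other splits of the libraries were counted for each comparison. Splitting 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. The number with as many genes as the real split was 1 in each comparison, with 3285, 4805 and 5823 genes in the real split and at most 7, 2 and 2 in the others. For gene lists it was also 1 each, with 21, 22 and 26 lists against at most 6, 11 and 13. For genes in opposite directions, 2 of 100 splits of the 9 libraries, the real one included, gave as many as the 1208 observed. The other gave 2096 and kept the 3 selenite libraries together as the middle group. Further splits gave 766 and 770, for reasons not tested. The count depends on which group is the middle one, and each split was counted with 1 choice. With the real groups and control as the middle, 1962 genes changed in the same direction in both treated groups. With selenite as the middle, 1452 were higher and 1701 lower than in both others. The splits thus do not show that the observed reversal is unusual.

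The spread within groups was small: at more than 10000 scaled counts the median coefficient of variation was 1.49% to 2.07%, against 0.492% to 0.510% from counting. If the libraries of a group came from 1 RNA sample or pool, carried-over transcripts should be equal between them. The sum over the pancreatic list differed 1.04-fold between the highest and lowest selenite library, which is consistent with 1 sample or pool. The spermatid list, chosen after the data were seen, also gave close sums in control replicates 1, 2 and 3, at 360, 366 and 361 scaled counts. Similar amounts in separate animals stay open for both lists, and no biological explanation was tested.

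Pancreatic and muscle transcripts appeared in selenite. Islet hormone genes, as markers of pancreatic tissue in the RNA, gave 0 that passed, but this decides nothing: of 7 listed, 4 were in the table and 0 had enough reads to be tested, so the expected outcome had been set wrongly. Their reads were 0 in control, 0 in β-CYP and 17 in selenite, so pancreatic tissue may have been present. The ratio of muscle to pancreatic sums differed 1.06-fold between the selenite libraries, but each sum hardly varied, so a single contaminating tissue and separate sources cannot be told apart. Expression in the liver under treatment, confounded with the group, was not tested.

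Some transcripts were present in 1 group and absent from another, such as H2-Ea-ps with 171 reads in control, 0 in β-CYP and 3173 in selenite. Between selenite and β-CYP, the median absolute log2 change of 31 H2 genes, 0.833, lay at percentile 100 of 10000 random lists matched on mean (median 0.267), as a difference of MHC haplotype between the groups would give, and that may be the source. A difference of genotype between the groups would be confounded with the treatment. Interferon would move its own targets as well, but the signed median of that list was -0.11 (SD 0.42 over 26 genes), with 4 up and 5 down. This argues only against a shared one-way move of interferon targets as the whole source, while immune cells stay open. The absolute changes of that list were not compared with those of the H2 genes. For Mup13 and Mup-ps19, a shift of reads to near-identical copies would raise these, but the other 39 Mup genes changed by -955% of the loss of 33496 scaled counts, and so large a fall of the family would hide such a shift, so the expected outcome had been set wrongly. The 5 other Mup genes that rose gained 12128 scaled counts, 36.2% of that loss. Among them, Mup21 rose from 2591 ± 106 to 14712 ± 490 scaled counts. A shift of reads and a biological loss, which was not tested, thus cannot be told apart.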
